A study of Mus musculus with 10 samples.

How the data were processed

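Messenger RNA levels were measured with single-channel arrays carrying 41345 probe sets, with 10 hybridised samples of sorted mouse regulatory T (Treg) cells, 5 wild type (WT) and 5 LKB1-deficient. Per the labels' protocols, the cells were sorted from mixed bone marrow chimeras and lysed without culture, total RNA was purified on Qiagen RNeasy Micro columns, and a few nanograms were amplified with the NuGEN WTA Pico v2 kit and labelled with biotin through the NuGEN Encore Biotin module. The deposited values are on a log2 scale. Per the submitters' processing notes, RMA (robust multi-array average: background correction, quantile normalization and a summary over the probes of each probe set) and Partek 6.6 were used, and the order and settings of these steps are not given in the sources used here. The small RNA input made amplification necessary, which compresses or distorts the levels of some transcripts, and quantile normalization gives all arrays nearly the same distribution, so that a shift shared by all transcripts cannot be seen. The deposited table carries no detection calls, so a value near the lower end of the scale cannot be told from background.

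Probe sets were named through the platform annotation. Of the 41345 probe sets, 23521 named exactly 1 gene symbol, 1814 named several and 16010 named none. Probe sets with several names were given no gene. The Entrez identifiers of 23328 of the singly named probe sets were present in the RefSeq gene table of GRCm38.p6, and no symbol differed from it. That table served for names only, since no genome build is given for the array. A gene measured by more than 1 probe set (1082 genes) was represented by the probe set with the highest mean over all 10 arrays, which left 22180 genes. No gene was removed for a low level. No array contributed values from outside the series.

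Groups and replicate numbers were taken from the sample titles. The LKB1-deficient arrays were compared with the WT arrays in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, all 10 arrays and no covariate, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 22180 genes. The moderated variances carried 4.36 prior degrees of freedom. Differences are given as LKB1-deficient minus WT on the log2 scale with the standard error (SE) of the fit, and group means with the standard deviation (SD) of 5 arrays. Adjusted p-values of genes come from this limma model unless another fit is named beside them. The number of arrays limits the precision. The labels do not say whether the arrays of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

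Before the data were examined, 38 gene lists were fixed: 27 for Treg, metabolic and signalling functions, 10 for cell types other than Treg cells, and 1 for T cell identity. They were drawn from general knowledge and from what is known of the study, and 629 of their 703 entries were measured. The 36 lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, which compares a list with all other genes, with Benjamini-Hochberg adjustment over the 36 lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, were run beside it. The genes named in the text were chosen by a rule fixed at the same time: Stk11; the 12 largest increases and 12 largest decreases among called genes whose groups did not overlap, passing over genes known only by a clone or predicted name and antigen receptor segments; 22 fixed genes; and up to 4 members with the smallest p of each list discussed, with the highest member of the lists of other cell types. Of the 22 fixed genes, 1 is not reported here.

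Alternatives fixed before the data were examined were the mean of all probe sets of a gene, removal of the dimmest 40% of genes, subtraction of array medians, a second quantile normalization, a trended robust prior, variances without moderation, array quality weights, the replicate number as a block, the submission set as a block, each array left out in turn, every probe set tested on its own, the other list tests and an adjusted p under 0.01. The submission set refers to the running codes in the sample descriptions, in which replicates 1 to 3 of both groups form a series of 6 samples (set 1) and replicates 4 and 5 a series of 4 (set 2). What the codes stand for is not stated. Added after seeing the data were fits of set 1 and set 2 alone, a fit with the per-array means of the macrophage and B cell lists as covariates, and a fit without LKB1-deficient arrays 1, 4 and 5.

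The same code was tested on simulated data with the measured means and residual spreads of the 22180 genes, 5 against 5 arrays, with 200 genes changed. It recovered 48% of genes changed by 0.5 on the log2 scale, 88% of those changed by 1, 94% of those changed by 1.5 and all 50 of those changed by 2, and it called 13 of 21980 unchanged genes. These shares hold for independent normal errors, without the array differences described in the report. A simulated list shifted by -0.3 was called by camera, and 0 of 35 unchanged lists were. The errors were independent here too, so this does not test the preset correlation. In the measured lists the estimated correlation ran from -0.02 to 0.73.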

Results

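Transcript levels were measured in Treg cells, the Foxp3-expressing CD4 T cells that restrain immune responses, from mouse bone marrow chimeras that held donor cells of more than 1 genotype. There were 5 WT and 5 LKB1-deficient samples, each hybridised to its own array. LKB1, encoded by Stk11, is a protein kinase that activates AMPK and related kinases. The comparison addresses which transcripts of Treg cells depend on LKB1. Array medians over all probe sets lay between 4.83 and 4.86 on the log2 scale on WT arrays. On LKB1-deficient arrays they lay between 4.88 and 4.94, so the medians of the groups did not overlap. WT arrays correlated with one another at r = 0.990 to 0.993 over genes, and LKB1-deficient arrays at 0.969 to 0.989, so the second group was the more variable.

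Stk11 itself had a mean log2 signal of 6.78 ± 0.15 (SD, n = 5) in WT and 6.42 ± 0.37 (SD, n = 5) in LKB1-deficient cells, from 1 probe set (17235180, Entrez gene 20869). The difference of -0.36 (SE 0.16) did not pass the limma test (adjusted p = 0.335). LKB1-deficient arrays 2 and 3 were at 6.01 and 6.05, below the lowest WT array at 6.61, and array 1 was just below it at 6.57. LKB1-deficient arrays 4 and 5, at 6.71 and 6.78, lay within the WT range. In set 2 they were below the WT arrays of that set, at 6.95 and 6.92. Which exons were deleted, and whether this probe set covers them, is not given in the sources used here, so the probe set may check the labels only in part. With the macrophage and B cell list means as covariates the difference was -0.77 (adjusted p = 0.0135), and without LKB1-deficient arrays 1, 4 and 5 it was -0.75 (adjusted p = 0.0178). Both fits were chosen after the data were seen. LKB1-deficient arrays 1, 4 and 5 had the highest Stk11 of their group, so leaving them out had to enlarge the difference. The covariates were highest on the same arrays. All values for LKB1-deficient cells refer to the arrays labelled so.

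LKB1-deficient Treg cells differed from WT in 236 genes, of which 52 were higher and 184 lower. The largest increase was that of Epas1, which encodes the hypoxia-inducible transcription factor HIF-2 alpha, at 3.82-fold (log2 difference 1.93, SE 0.19, adjusted p = 9.9e-04). Among the other 11 of the 12 largest increases were Pde7b (1.90) and Pde3b (1.53), which encode phosphodiesterases that hydrolyse cyclic AMP, Adcy6 (1.0), an adenylyl cyclase, and Plaur (1.86), the urokinase receptor. They also included Ifngr1 (1.25) and Il12rb2 (1.06), subunits of the interferon gamma and interleukin 12 receptors, Elovl6 (1.07, adjusted p = 2.3e-04), which elongates fatty acids, Cd24a (1.43), Snora23 (1.04), and the receptor genes Klrd1 (1.53) and Clec7a (1.44), typical of natural killer (NK) and myeloid cells. The largest decrease was in Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase, which was 3.72-fold lower (log2 difference -1.89, SE 0.14, adjusted p = 2.0e-04). Itgae, encoding the CD103 integrin chain (-1.29), Nrp1, the neuropilin-1 receptor of many Treg cells (-1.27), Il10, the anti-inflammatory cytokine (-1.21), Ptger2, a prostaglandin E2 receptor (-1.18), and Rgs16, a regulator of G protein signalling (-1.36), fell as well. The others of the 12 largest decreases were Khdc1a (-1.85), Pianp (-1.45), Cst7 (-1.44), Ddx43 (-1.33), Zfp97 (-1.12) and Eea1 (-1.11).

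Of the called genes, 46 of the 52 higher and 181 of the 184 lower ones had no overlap between the groups, and over all genes 1044 (4.71%) had none, where chance gives 0.794%. A change of at least 2-fold was reached by 18 higher and 21 lower genes, and 3103 genes had an unadjusted p under 0.05. Each array left out in turn moved the counts. They were 17 higher and 48 lower without WT 1, 17 and 61 without WT 2, 15 and 41 without WT 3, 8 and 30 without WT 4, and 24 and 64 without WT 5. They were 180 and 340 without LKB1-deficient 1, 47 and 142 without LKB1-deficient 2, 41 and 118 without LKB1-deficient 3, 23 and 84 without LKB1-deficient 4, and 41 and 123 without LKB1-deficient 5. In all 10 of these fits 37 of the 236 genes stayed past the threshold, 8 higher and 29 lower, among them Epas1, Elovl6, Pde3b, Gucy1a1, Rgs16, Itgae, Nrp1, Pianp and Zfp97. Of the other named genes, Pde7b, Plaur and Klrd1 stayed past in 9 of the 10, Cd24a and Cst7 in 7, Snora23, Ptger2 and Eea1 in 5, Adcy6 and Khdc1a in 4, Clec7a in 3, Ifngr1, Il10 and Ddx43 in 2 and Il12rb2 in 1. Their adjusted p reached 0.122 at most, in Ddx43. With a second quantile normalization 67 genes were higher and 103 lower, so the share of higher genes was 39.4% against 22.0%. With the replicate number as a block 14 were higher and 36 lower, and without moderation of the variances 17 and 132.

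**Figure D1:**
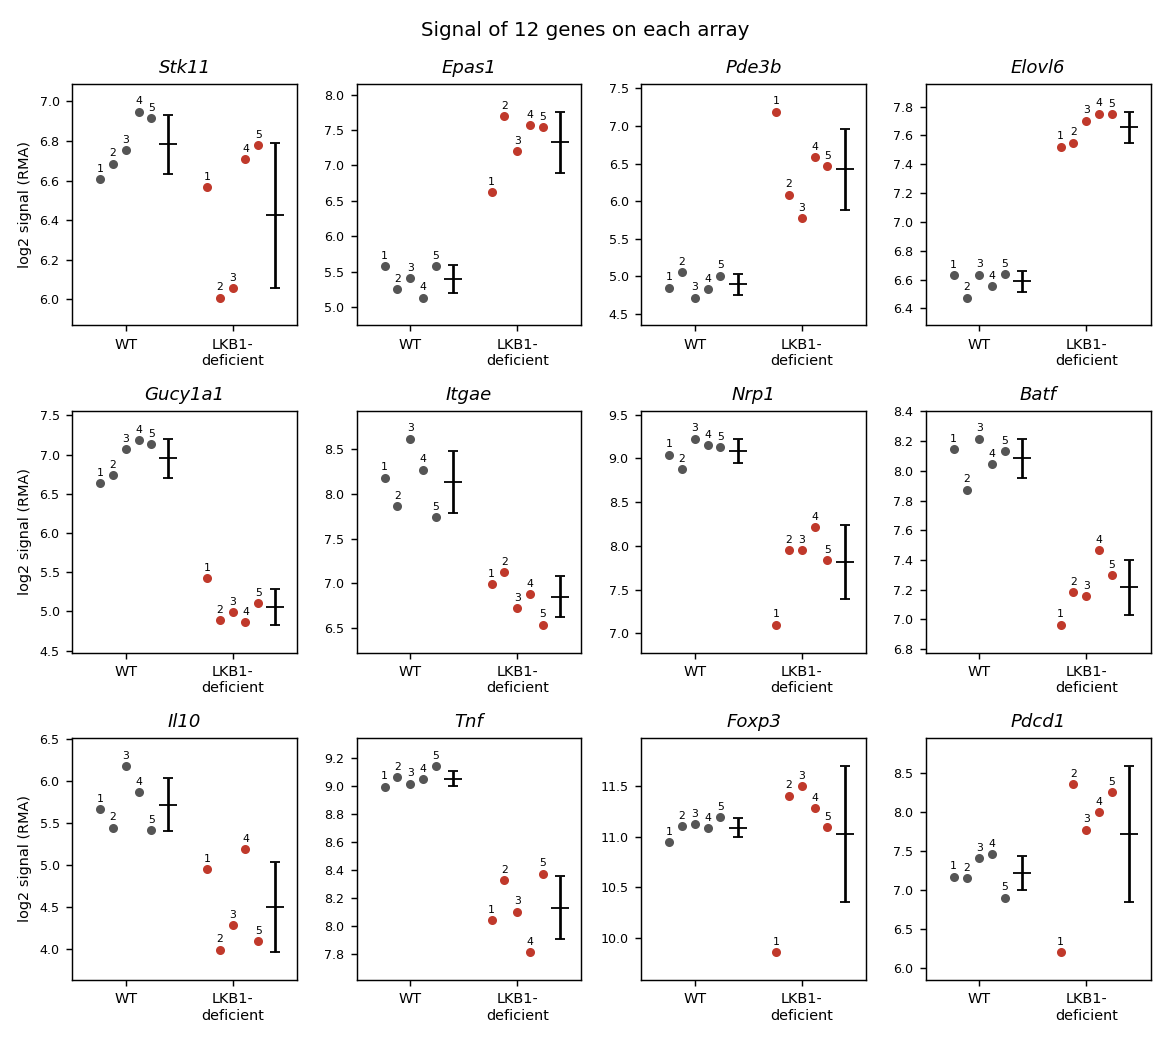
Log2 signal (y axis) of 12 genes on the 5 WT arrays (grey) and 5 LKB1-deficient arrays (red), numbered by replicate, with the group mean and SD in black beside the points. Epas1, Pde3b and Elovl6 were higher and Gucy1a1, Itgae, Nrp1, Batf, Il10 and Tnf lower on all 5 LKB1-deficient arrays than on any WT array, whereas Stk11, Foxp3 and Pdcd1 overlapped; LKB1-deficient array 1 was lowest for Foxp3 at 9.86 and for Pdcd1 at 6.20.

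Transcripts typical of other cell types were higher than on WT arrays on some of the LKB1-deficient arrays, mainly 1, 4 and 5. On arrays 4 and 5 the mean of the monocyte, macrophage and dendritic list was 8.62 and 8.72, against 6.30 to 6.70 on the WT arrays and 6.93, 6.44 and 6.74 on LKB1-deficient arrays 1, 2 and 3. The B and plasma cell list had means of 8.43, 8.52 and 8.84 on LKB1-deficient arrays 1, 4 and 5, against 6.80 to 7.17 on WT arrays. The NK list was at 6.48, 6.51 and 6.67 on the same 3 arrays, at 5.42 and 5.66 on LKB1-deficient arrays 2 and 3 and at 5.25 to 5.48 on WT arrays. The conventional CD4 T cell list was at 8.07 on LKB1-deficient array 1 and at 7.28 and 7.42 on arrays 4 and 5, against 7.15 to 7.26 on WT arrays, and the erythroid and platelet list, with 3 measured members and no list test, at 7.15 and 7.06 on LKB1-deficient arrays 4 and 5 against 5.28 to 5.44. Over all arrays, 4 of these lists were higher in the camera test: monocyte, macrophage and dendritic (adjusted p = 1.0e-07), B and plasma (2.2e-05), NK and innate lymphoid (9.2e-05) and CD8 T (0.0456). With an estimated correlation their adjusted p was 0.261, 0.203, 0.141 and 0.269. The CD8 T list stayed called in 3 of the 10 leave-one-out fits (adjusted p 0.0111 to 0.111) and the other 3 in all 10. Within set 1 the macrophage list was not called (adjusted p = 0.473), and within set 2 it was (1.6e-29). Single members seldom passed: Cd8a rose (0.77, adjusted p = 0.0423, past in 3 of the 10 leave-one-out fits) and so did Klrd1 and Pde3b, while Lyz2 (1.17), Itgax (1.43), Tyrobp (1.29), H2-Aa (1.29) and Jchain (1.77) did not pass. Pde3b, 1 of the largest increases, belongs to the conventional CD4 T list. It was at 7.19 on LKB1-deficient array 1 and at 5.77 to 6.59 on the other 4, against 4.72 to 5.06 on WT arrays, and its difference was 1.09 (adjusted p = 0.0121) with the macrophage and B cell list means as covariates and 1.04 (0.0077) without LKB1-deficient arrays 1, 4 and 5. The neutrophil (adjusted p = 0.0569, called within set 1 at 0.0472 and in 4 of the 10 leave-one-out fits), conventional CD4 T (0.277), mast cell and basophil (0.387) and stromal, endothelial and epithelial (0.427) lists were not called, and the gamma-delta T cell list had 3 measured members, with a median difference of 0.14, and no list test. The T cell identity list, with 7 of 9 estimates negative, was lower (adjusted p = 0.0300, and 0.496 with an estimated correlation), Zap70 being at -0.28 and Cd3e at -0.16, neither past the threshold. The call ended without LKB1-deficient array 1 (adjusted p = 0.140), 4 (0.0676) or 5 (0.113). T cell identity had a positive shift without LKB1-deficient arrays 1, 4 and 5 (adjusted p = 0.719), and none of the lists of other cell types was called there.

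Without LKB1-deficient arrays 1, 4 and 5, 154 genes were higher and 203 lower, and 125 of the 236 genes stayed past the threshold, 36 higher and 89 lower. With the macrophage and B cell list means as covariates the counts were 97 and 169, with 109 genes shared. These 2 fits are not separate checks, since both list means were highest on LKB1-deficient arrays 1, 4 and 5. All 236 kept their sign in both fits. For genes whose groups did not overlap, leaving out arrays could not turn the sign, so this adds no support. Klrd1 and Clec7a did not pass in either (adjusted p = 0.0986 and 0.167 with the covariates, 0.0558 and 0.0894 without the 3 arrays), and Clec7a went from 1.44 to 0.65 and 0.67. Cd24a went from 1.43 to 0.82 and 0.86, past in both. Of the other called genes named here, Ddx43, Izumo1r, Btla, Myc, Gart, Cad, Hadh, Fasn, Sqle, Pprc1, Rplp0, Shmt2, Mcm6 and Cd8a did not pass in either fit, nor Khdc1a with the covariates. A lost call does not mean a smaller difference: Gart was at -0.55 with all arrays, -0.56 with the covariates and -0.52 without the 3 arrays, Mcm6 at -0.53, -0.52 and -0.53, Pprc1 at -0.48, -0.45 and -0.44, and Rplp0 at -0.61, -0.65 and -0.69, whereas Hadh went from -0.58 to -0.37 in both and Izumo1r from -0.70 to -0.49 and -0.47. Of the genes not called with all arrays, Stk11, Tigit, Lag3, Ifng, Tnfrsf9 and Gata3 passed in both, and Tnfrsf18, Tnfrsf4 and Suclg2 without the 3 arrays. The 3 arrays were the highest of their group for Stk11, Tigit, Lag3 and Ifng and the lowest for Tnfrsf9, Tnfrsf18 and Tnfrsf4. Leaving them out had to enlarge those differences, so these passes add no support. With the submission set as a block 70 genes were higher and 190 lower. Within set 1, 3 arrays against 3, limma called 0 genes at the adjusted threshold and 2247 at an unadjusted p under 0.05. Within set 2, 2 against 2, it called 423 higher and 46 lower genes, of which 40 were among the 236.

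Transcripts of Treg cells that mark effector function were lower. In the effector Treg list 5 of 16 measured members fell, 0 rose and 11 did not pass, with a median difference of -0.63 (camera adjusted p = 1.6e-08, and 0.141 with an estimated correlation). Adjusted over the list alone, 9 fell. Batf, a transcription factor of effector Treg cells, was 1.83-fold lower (-0.87, SE 0.11, adjusted p = 0.0074), and Ccr4, a skin and tissue homing receptor, fell by 0.87 on the log2 scale (adjusted p = 0.0342), beside Itgae and Il10. In the Treg signature list 4 of 22 members fell and 0 rose, with a median of -0.19 (adjusted p = 6.8e-06, and 0.30 with an estimated correlation), and 8 fell when adjusted over the list alone. Nrp1, Itgae, Nt5e, the CD73 ectoenzyme (-1.10, adjusted p = 0.0129), and Izumo1r, folate receptor 4 (-0.70, adjusted p = 0.0209), were the 4. These counts moved with the arrays. Without LKB1-deficient array 1 the Treg signature had 3 members higher and 7 lower (median -0.10), with the covariates 1 and 5 (median -0.056) and without LKB1-deficient arrays 1, 4 and 5 it had 3 and 4 (median -0.043). The effector Treg list had 6, 8 and 9 members lower in these fits and 0 higher. The call of the Treg signature ended with the covariates (adjusted p = 0.107) and without LKB1-deficient arrays 1, 4 and 5 (0.564), whereas that of the effector Treg list held in both. The effector Treg list mean was 6.96, 6.99 and 6.88 on those 3 arrays and 6.42 and 6.36 on LKB1-deficient arrays 2 and 3. Leaving the 3 out therefore had to enlarge its decrease, and the covariates were highest on them. Within set 1 both lists were called, and within set 2 the Treg signature was (0.0131) and the effector Treg list was not (0.0570). Batf, Itgae and Nrp1 stayed past in all 10 leave-one-out fits, Nt5e in 9, Izumo1r in 5 and Ccr4 in 3 (up to 0.0995). Foxp3, the lineage factor of Treg cells, was at 11.09 ± 0.09 (SD, n = 5) in WT and 11.03 ± 0.67 (SD, n = 5) in LKB1-deficient cells, a difference of -0.06 (95% confidence interval -0.61 to 0.49, adjusted p = 0.947). Its sign turned to 0.23 without LKB1-deficient array 1, not past the threshold. Il2ra (-0.16), Ctla4 (-0.16) and Ikzf2 (-0.12) did not pass either, and their signs turned without LKB1-deficient arrays 1, 4 and 5.

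The receptors Pdcd1 (PD-1), Tnfrsf18 (GITR), Tnfrsf4 (OX40) and Tnfrsf9 (4-1BB) had differences of 0.50, 0.33, 0.26 and 0.40 with adjusted p of 0.549, 0.516, 0.566 and 0.558. Each was above all WT arrays on 4 of the 5 LKB1-deficient arrays and below them on array 1. Without LKB1-deficient array 1 the differences were 0.88, 0.55, 0.45 and 0.72 with adjusted p of 0.0116, 0.0150, 0.0458 and 0.0041. Gata3, a transcription factor of type 2 helper cells, behaved alike, at 0.37 (adjusted p = 0.271) and 0.53 (adjusted p = 0.0080) without that array. Array 1 was the lowest of its group for these receptors and Gata3, so leaving it out had to enlarge the differences. Of the 10 leave-one-out fits, this was the only 1 in which they passed. In the costimulatory and coinhibitory receptor list 1 of 19 members fell, Btla (-0.47, adjusted p = 0.0398, past in 3 of the 10 leave-one-out fits), and 0 rose, and the list was not called (adjusted p = 0.387). It had 4 members higher and 2 lower without LKB1-deficient array 1, 1 and 2 with the covariates and 3 and 2 without LKB1-deficient arrays 1, 4 and 5. Tigit (-1.46, adjusted p = 0.171), Icos (-0.40) and Lag3 (-0.64) did not pass, and Tigit did without LKB1-deficient array 1 (-1.84, adjusted p = 0.0372). With the covariates Tigit was at -2.51 (adjusted p = 0.0092) and Lag3 at -1.36 (0.0027), and without LKB1-deficient arrays 1, 4 and 5 they were at -2.50 (0.0141) and -1.32 (0.0068). Tnf fell (-0.92, adjusted p = 0.0061) in all 10 leave-one-out fits, while Ifng (-0.65, adjusted p = 0.160) and Il4 (0.17) did not pass. Ifng did with the covariates (-1.17, adjusted p = 0.0052) and without the 3 arrays (-1.15, adjusted p = 0.0093). For Tigit, Lag3 and Ifng these 3 arrays had the highest values of the LKB1-deficient group, so leaving them out had to enlarge the decreases. The covariates were highest on the same arrays. Tigit was highest on LKB1-deficient array 1, at 8.04, so the fit without that array was forced alike. The helper T cell cytokine list was not called (adjusted p = 0.277). The resting or central T cell list was higher (adjusted p = 0.0036, and 0.24 with an estimated correlation), with 9 of 12 estimates positive and 0 members past the threshold over all genes, 5 over the list alone. The list was not called within set 2 (adjusted p = 0.405). Satb1 was at 0.38, Ccr7 at 0.37 and Il7r at 0.60, and Il7r was at 0.14 both with the covariates (adjusted p = 0.734) and without the 3 arrays (0.668).

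Genes of energy and biosynthetic metabolism were lower as lists, with few members past the threshold singly. All 37 measured oxidative phosphorylation genes had negative estimates with a median of -0.22 (camera adjusted p = 3.0e-11) and none passed. All 20 tricarboxylic acid cycle genes did too, with a median of -0.20 (3.3e-07) and none past. With an estimated correlation both had an adjusted p of 0.141. Suclg2 (-0.59), Pdha1 (-0.48), Ndufa10 (-0.37) and Uqcrfs1 (-0.34) had the smallest p in these lists. In nucleotide synthesis 4 of 19 members fell: Nme1 (-0.70, adjusted p = 0.0089), Gart (-0.55), Ppat (-0.51) and Cad (-0.59), which catalyse steps of purine and pyrimidine synthesis. Its median was -0.35 (adjusted p = 5.4e-10), and it was the list that also passed with an estimated correlation (adjusted p = 0.0374). In cholesterol and fatty acid synthesis Fasn (-0.50), fatty acid synthase, and Sqle (-0.60), squalene epoxidase, fell among 20 members (list adjusted p = 1.7e-08, and 0.112 with an estimated correlation). In fatty acid oxidation Eci1 (-0.85) and Hadh (-0.58) fell among 20 (3.8e-04, and 0.141). Glycolysis had 14 of 15 negative estimates and no member past the threshold, Gapdh being at -0.27 (0.0020, and 0.183). Mitochondrial biogenesis and dynamics had 1 of 23 lower, Pprc1 (-0.48; 0.0015, and 0.0874), and cytosolic ribosomal proteins 1 of 24 lower, Rplp0 (-0.61), with Rps4x at -0.37 and all 24 estimates negative (1.6e-08, and 0.0902). Cs, citrate synthase, was at -0.25 and Ppargc1a at 0.17, neither past. The counts of lower members moved between fits. Without LKB1-deficient array 1, with the covariates and without LKB1-deficient arrays 1, 4 and 5 they were, in that order, 9, 3 and 4 for nucleotide synthesis, 4, 1 and 2 for cholesterol and fatty acid synthesis, 2, 1 and 1 for fatty acid oxidation, 1, 1 and 0 for mitochondrial biogenesis, 3, 0 and 0 for ribosomal proteins and 1, 0 and 1 for the tricarboxylic acid cycle. No member of the 8 lists was higher in these fits, and those of oxidative phosphorylation and glycolysis stayed at 0 lower. The 8 lists stayed called in every leave-one-out fit, with the covariates and without LKB1-deficient arrays 1, 4 and 5, and their means lay below every WT array on all 5 LKB1-deficient arrays. Within set 1 all 8 were called, and within set 2 the 4 lists of oxidative phosphorylation, nucleotide synthesis, cholesterol and fatty acid synthesis and ribosomal proteins were, with an adjusted p of 0.0540 for the tricarboxylic acid cycle, 0.0593 for mitochondrial biogenesis, 0.528 for glycolysis and 0.357 for fatty acid oxidation. Of the single genes, Nme1 stayed past in all 10 leave-one-out fits, Eci1 in 6, Gart in 5, Ppat and Hadh in 4, Fasn and Sqle in 2, and Cad, Pprc1 and Rplp0 in 1 (up to 0.130).

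Of the other lists, cell division was lower (adjusted p = 0.0058, and 0.313 with an estimated correlation), with 1 of 26 members past the threshold, Mcm6 (-0.53), a replication helicase subunit, and Mki67 at -0.21. Within set 2 alone its direction turned (adjusted p = 0.667). Chemokine receptors and adhesion was lower (0.0204, and 0.141), with Itgae and Ccr4 lower and Cxcr4 (0.93, adjusted p = 0.0192), the receptor of the chemokine CXCL12, higher. The interferon response list was higher (0.0039, and 0.482), with 18 of 23 estimates positive and 1 member past, Oas2 (0.84, adjusted p = 0.0235), an antiviral enzyme, and its call ended without LKB1-deficient array 2 (0.0576). Myc, a growth-promoting transcription factor, fell by 0.76 on the log2 scale (adjusted p = 0.0398), and stayed past in 3 of the 10 (up to 0.109). From -0.76 (SE 0.15) its difference went to -0.48 (SE 0.10, adjusted p = 0.0512) with the covariates and to -0.47 (SE 0.10, adjusted p = 0.0557) without LKB1-deficient arrays 1, 4 and 5. The Wnt and beta-catenin list was not called (0.892) and Ctnnb1 was at -0.07. The list of the LKB1 complex and AMPK-related kinases was not called (0.892), with Sik1 at 0.43 (adjusted p = 0.0838), above all WT arrays on all 5 LKB1-deficient arrays, and Prkaa1 at 0.23. In the immediate early list Egr2 (-0.50) and Junb (-0.68) fell, and Crem (0.55) and Rgs2 (0.71) did not pass (list 0.748). The cytokine receptor list (0.409) had 2 higher members, Ifngr1 and Il12rb2. The amino acid response (0.109, Shmt2 at -0.48 past), BCL2 family (0.775, Bcl2 at -0.13), p53 (0.550), NF-kB (0.649), TGF-beta (0.748), autophagy and lysosome (0.0902) and heat shock (0.370) lists were not called. The heat shock list was called lower within set 1 (1.0e-05), with the covariates (1.7e-04) and without LKB1-deficient arrays 1, 4 and 5 (0.0015), and higher within set 2 (1.9e-04). The amino acid response list was called lower with the covariates (0.0191) and without the 3 arrays (0.0120), and the autophagy and lysosome list higher within set 2 (1.1e-05). Of the 10 leave-one-out fits, 3 called the autophagy and lysosome list, 1 the amino acid response list and 1 the heat shock list. The chemokine receptor list was not called within set 2 (0.298), nor the interferon response list within set 1 (0.0905). Of these genes Egr2 stayed past in 7 leave-one-out fits, Cxcr4 in 6, Oas2 in 5, Mcm6 in 3 and Junb and Shmt2 in 2 (up to 0.112). In the fits without LKB1-deficient array 1, with the covariates and without the 3 arrays, the interferon response list had 3, 1 and 3 members higher. The immediate early list had 4, 2 and 2 higher and 3, 2 and 3 lower, Crem being past in the first (0.61, adjusted p = 0.0176). The chemokine receptor list had 1 higher in each and 3, 5 and 5 lower, the cytokine receptor list 2 higher in each and 2, 1 and 1 lower, the amino acid response list 3, 1 and 1 lower and the cell division list 1, 0 and 0 lower. Camera's direction was opposite to the list median for the Wnt, AMPK-related kinase and BCL2 lists, and the mean and median differed in sign for the BCL2 and immediate early lists.

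**Figure D2:**
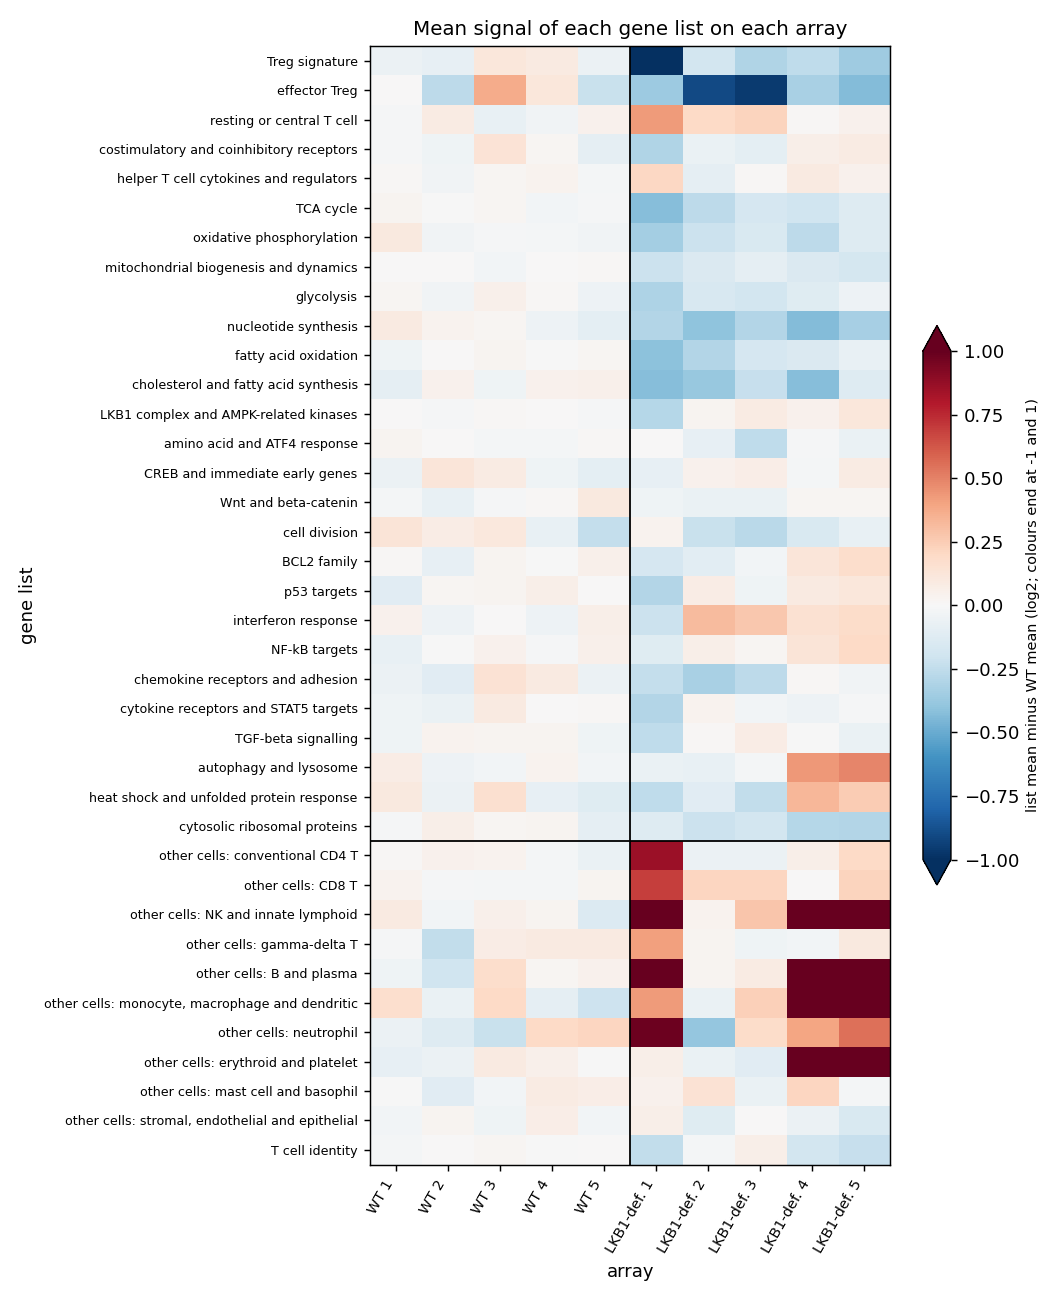
Mean log2 signal of 38 gene lists (rows) on each of the 10 arrays (columns), as the difference from the mean of the WT arrays; red is higher, blue lower, and colours end at -1 and 1. The metabolic lists are below the WT arrays on all 5 LKB1-deficient arrays, while the monocyte, macrophage and dendritic list reaches 8.62 and 8.72 on LKB1-deficient arrays 4 and 5 and is at 6.44 on array 2.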

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

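Except for the count of other splits of the samples, the tests weighed here were chosen after the results they examine had been seen. Among 254 groups of 5 values, 18 had 1 array far from the others by Dixon's test, where chance flags about 1 in 20, or 12.7, and 11 of the 18 were LKB1-deficient array 1. That array was low for Ifngr1 (9.69 against 10.98 to 11.07 on the other 4), Foxp3 (9.86), Pdcd1 (6.20), Tnfrsf18 (9.68), Tnfrsf9 (8.30), Gata3 (8.16) and Ctnnb1 (7.61). It was low in the means of the Treg signature (8.17), the AMPK-related kinases (6.70) and the cytokine receptors (8.50), and high in that of conventional CD4 T cells (8.07). LKB1-deficient array 3 stood apart for Prkaa1 (8.38) and Ndufa10 (9.17). WT 1 stood apart for Sik1 (8.58), Eci1 (7.42) and the oxidative phosphorylation mean (9.23), WT 5 for Ppat (8.58) and WT 3 for the mitochondrial biogenesis mean (7.44).

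The difference between the genotypes was itself different in sets 1 and 2 for 240 genes in an interaction test, 238 of them in the direction of a higher difference in set 2. Among the genes chosen by the naming rule these were Jchain (by 3.15 on the log2 scale), Lyz2 (1.59) and Ppbp (2.60). Csf1r (3.40) and C1qa (3.25), picked later, were others. Among the lists they were the means of autophagy and lysosome (0.51), heat shock (0.67), monocyte, macrophage and dendritic (2.22) and erythroid and platelet (1.75). Among probe sets without a single gene name, which the report leaves aside, 10 were higher and 20 lower in a fit of every probe set.

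Chance assignment of the arrays is argued against for the count of 236 genes: 1 of 100 splits of the 10 arrays, the real one, gave as many, and the highest of the others gave 1. The 100 were drawn from 126 possible splits, and the test takes the arrays as independent. Since the labels do not say whether they came from separate animals, a chance difference between a few animals cannot be excluded.

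Macrophage transcripts were high on LKB1-deficient arrays 4 and 5. An effect of the genotype alone is argued against by the interaction, since the list mean differed by 2.22 more in set 2 than in set 1. Processing of set 2 as a whole is argued against by its WT arrays, whose highest list mean minus that of WT arrays 1 to 3 was -0.29. RNA of other cells in these samples may account for it: 13 of 14 measured markers were above every WT array on both arrays, with Csf1r at 10.55 and 10.49 against a WT mean of 7.22 and C1qa at 10.47 and 10.40 against 7.48, and 6 of the 10 lists of other cell types were above all WT arrays on both (Csf1r and C1qa were picked after their values were seen). A sort for Treg cells should remove such cells, so carry-over of fragments or doublets and a change limited to the LKB1-deficient samples of set 2 stay open, untested. A change in all animals of set 2 is argued against by WT arrays 4 and 5, whose macrophage list means were 6.41 and 6.30.

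Of the main gene lists 12 were lower: the 8 of metabolism and ribosomal proteins, effector Treg, Treg signature, cell division, and chemokine receptors and adhesion. They are not all separate results, as 26 genes were in more than 1 of the 38 lists. Itgae and Ccr4, the lower called members of the chemokine list, were also in the effector Treg list. Dilution by other cells is argued against as the whole cause, since 11 of the 12 stayed lower and called without LKB1-deficient arrays 1, 4 and 5, the Treg signature being the exception. Array scale is argued against for the lists in the same way, with 11 of 12 after a second quantile normalization. It is not excluded for single genes, since that step took the lower genes from 184 to 103. Correlation between the genes of a list stays open: with it estimated, 1 of the 12 kept its call as a list that moves apart from other genes, while fry, which allows for it but makes no comparison with other genes, called 10. An effect of LKB1 loss on these genes remains a hypothesis.

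Stk11 lay within the WT range on LKB1-deficient arrays 4 and 5. WT samples under a wrong label are argued against: the 100 genes with the smallest p among those lower in set 1 were at -0.61 and -0.56 on these arrays relative to WT arrays 1 to 3, and at -0.06 and -0.16 on WT arrays 4 and 5. Stk11 transcripts of other cells may contribute, as the difference was -0.77 with the list means as covariates. This cannot be told apart from any other feature of the same arrays. Foxp3, at 11.29 and 11.10 there, was not below the WT range, but it was below LKB1-deficient arrays 2 and 3, at 11.41 and 11.50. The T cell identity mean, at 10.79 and 10.74 there, was below every WT array, the lowest being at 10.95. Dilution of Treg transcripts on these arrays therefore stays open. Incomplete deletion, or exons outside the deleted part, were not tested.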

How the results depend on the processing

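The fits of set 1 or set 2 alone, with list means as covariates and without LKB1-deficient arrays 1, 4 and 5 were chosen after seeing the data. Counts are higher and lower genes, against 52 and 184. They were 72 and 284 without the dimmest 40% of genes, 49 and 285 with array medians subtracted, 67 and 103 quantile normalized again, 79 and 307 with a trended robust prior, 17 and 132 without moderation, 135 and 329 with array weights, 21 and 69 with every probe set on its own and 5 and 20 at an adjusted p under 0.01. Set 1 gave 0 and 0 (2247 genes at an unadjusted p under 0.05), set 2 gave 423 and 46, the covariates 97 and 169, and the fit without 3 arrays 154 and 203. Leaving out 1 array gave 8 to 180 higher and 30 to 340 lower genes. Genes changed at least 2-fold, 39 in the report, were 13 without moderation, 60 with array weights, 11 at an adjusted p under 0.01, 0 in set 1, 397 in set 2, 76 with the covariates, 78 without the 3 arrays and 15 to 63 with 1 array left out. With the replicate block 14 genes were higher, 36 lower and 22 changed at least 2-fold. Same-numbered arrays did not deviate together (r from -0.08 to 0.10), and 1 of 5 WT arrays correlated best with its own number, which gives no evidence of pairing by number and does not exclude it. The mean of all probe sets and the submission set as a block moved no count by more than 1.5 times.

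Of the main gene lists (2 higher, 12 lower), an estimated correlation left 0 and 1, fry 1 and 10, set 1 called 1 higher, and set 2 called 5 lower. Of the lists of other cell types with T cell identity (4 higher, 1 lower), an estimated correlation left 0 and 0 and fry 1 and 0. None of these was called without the 3 arrays, 0 and 0. T cell identity was the 1 lower list, and 0 were lower without dim genes, quantile normalized again, with array weights, in set 1 and in the leave-one-out fits with the lowest count, the highest being 1. Stk11 was -0.77 with the covariates and -0.75 without the 3 arrays, which had the highest Stk11 of their group, and it passed the threshold in both.

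Signs turned for these results, none of the genes being past the threshold in the report, and lists are given where the fit in the report or the one it is compared with called them. With array weights Foxp3 was 0.12 and Ctnnb1 0.018. Without LKB1-deficient array 1 Foxp3 was 0.23, Ikzf2 0.069 and Ctnnb1 0.085, with leave-one-out minima of -0.18, -0.23 and -0.13. In set 2 Foxp3 was 0.052, Ctnnb1 0.046, Ppargc1a -0.031 and Mki67 0.16, and the lists of cell division (adjusted p = 0.667) and heat shock (1.9e-04) turned. With the covariates Foxp3 was 0.32, Il2ra 0.21, Ctla4 0.15, Ikzf2 0.17, Il4 -0.042, Ctnnb1 0.0060, Bcl2 0.096 and Tyrobp -0.075, and T cell identity turned (adjusted p = 0.768). Without the 3 arrays the same values were 0.36, 0.23, 0.18, 0.20, -0.071, 0.053, 0.11 and -0.018, and 0.719. Lists not called in the report nor in these 2 fits also turned, such as autophagy and lysosome, with a median of 0.099 in the report, -0.086 with the covariates and -0.066 without the 3 arrays, and cytokine receptors, with -0.16, 0.016 and 0.024. The cause was not tested. A fit with fewer arrays has less power by construction, yet the counts rose without LKB1-deficient array 1. The deposited values carry no detection calls, so the limit that signal over background sets is unknown.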

Other observations

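The lists here were put together after the data were seen, and the tests on them were chosen then. Genes of ribosome assembly, the nucleolar steps that make ribosomes, were lower in LKB1-deficient cells. Gnl3 (-0.65), Pno1 (-0.76), Nhp2 (-0.68), Dkc1 (-0.53), Mdn1 (-0.47) and Imp3 (-0.47), noticed among the smallest p-values, prompted the list. Of the 40 other measured members, all 40 had negative estimates with a median of -0.34, and 6 passed the adjusted threshold, among them Utp20 (-0.73) and Nop58 (-0.59). The median was -0.34 without LKB1-deficient arrays 1, 4 and 5 as well. Mitochondrial ribosomal proteins had 66 of 71 estimates negative with a median of -0.27 and 6 lower members, and aminoacyl-tRNA synthetases 17 of 18 with a median of -0.24 and none past. Small nucleolar RNAs had a median of -0.18 with 1 member higher (Snora23) and 0 lower, and -0.04 without the 3 arrays. Camera called this list lower (adjusted p = 0.0014), but not with an estimated correlation (0.345) or without the 3 arrays (0.583). Cyclic nucleotide phosphodiesterases other than Pde3b and Pde7b had a median of 0.06, and the list was not called (camera adjusted p = 0.116).

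A joint decrease of ribosome assembly genes was tested without the 6 prompting genes. The other members were measured on the same arrays, so their removal does not make this an independent test. Utp20, which was kept, had the same limma adjusted p as Imp3, which was removed (0.0170). Camera gave an adjusted p of 7.0e-23 over the 5 added lists with the preset correlation and 4.9e-05 with an estimated correlation, and the list mean lay below every WT array on all 5 LKB1-deficient arrays. Mitochondrial ribosomal proteins (0.0050) and the synthetases (0.0087) also passed with an estimated correlation. These lists were tested with no member removed, so the 6 lower mitochondrial ribosomal proteins stayed in. The cause of the decrease was not tested.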
